A study of Oryza sativa with 6 samples.

How the data were processed

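Leaf blades of rice (Oryza sativa) were measured on 6 arrays of the Affymetrix Rice Genome type, 3 of an Os-LBD37 overexpressor line and 3 of an empty vector line. Per the labels, the 5th and 6th leaf blades of hydroponically grown plants were taken, and biotin-labelled cRNA was made from 10 ug of total RNA. The groups come from the titles and source names; the description field of the overexpressor samples names the control and was not used for grouping.

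The values are probe set intensity as deposited by the authors, on a linear scale. Each array had a trimmed mean of 500.1 after removal of 2 percent at each end, while quantiles differed between arrays, so each array had been scaled by 1 factor. The summarization software is not given in the sources used here. No array was a copy of another: at most 0.00349 percent of values were identical in any pair. For arrays, their number limits the precision.

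Of 57381 probe sets, 187 were controls and were left out of the fits, which left 57194. A name table paired 22436 with 1 gene and 95 with several genes, and 34663 had none; probe sets with several or no genes stayed in the probe set comparison only. These covered 17905 genes, of which 2453 had a name other than a locus identifier. Names came from the gene table of assembly ASM3414082v1. No name in these tables is that of Os-LBD37, so the planned report of its probe sets was not analysed here. The rice locus written for it in the plan came from memory and was not checked.

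Intensities were taken as log2(intensity + 16). limma 3.58.1 in R 4.3.3 fitted the difference, overexpressor minus empty vector, with lmFit and eBayes (variance trend), 2-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. Errors of log2 changes are the fit's standard errors (SE). Each gene was represented by the probe set with the highest mean over all 6 arrays, and adjustment was repeated over genes. An exact permutation test of 3 against 3 arrays cannot go under p = 0.1, so it was used only for control probe sets. The p-values measure only the spread between these samples: the labels speak of independent hybridizations and do not say that these are separate plants.

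Background on each array was the 95th percentile of 132 control probe sets for transcripts absent from rice. Where a gene was not above it on any array of a group, the fold is given as a bound ("at least"), made from the bright group's mean against the higher of background and own value on each dim array.

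The tests, thresholds, alternatives and 46 gene lists were set before the data were examined. The tables hold names and no descriptions, so list members were assigned from symbols and synonyms before any comparison was run. Genes without a matching name are outside the lists, so counts of list members are not counts of whole families. 39 lists were tested, 4 had under 3 members and 3 had none. 7 further lists, of aquaporins, endoplasmic reticulum chaperones, potassium transporters, plastid proteases, metal transporters, abscisic acid and stress kinases, and PP2C phosphatases, were added at that point and adjusted as a family of their own. limma camera used a preset correlation of 0.01, and again an estimated one; fry tested direction. Genes named are those with a name that passed, with non-overlapping groups and a higher group above the median probe set, up to 12 in each direction, and the members of lists with the smallest p. No other probe set of a named gene passed with the opposite sign.

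Whether the replicate numbers pair the arrays was checked on deviations from each line's mean. Arrays of the same number had correlations of 0.281, 0.35 and 0.205, and those of different numbers ranged from -0.362 to 0.24. These ranges overlap, since empty vector replicate 3 had 0.24 with overexpressor replicate 1 and 0.205 with overexpressor replicate 3. The replicate 2 arrays had 0.35 with each other, and -0.362, -0.307, -0.197 and -0.144 with arrays of other numbers. Deviations within a line cancel, so a shift of replicate 2 also draws replicates 1 and 3 together in this measure. The difference of replicates 1 and 3, which leaves out replicate 2, had a correlation of 0.22 between the lines over expressed genes. With 1 array per number and line, the check does not settle the pairing, which is taken from the replicate numbers in the titles. A fit with the number as a block is given where it changes a call or moves a count.

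The functions were tested on simulated arrays of 57194 probe sets with the real means and 200 changed probe sets. With residual spreads and only 2-fold and 4-fold changes, tried first, 0 percent of either were recovered. Larger changes and a moderated spread were then added, and all 4 combinations were kept. With 16-fold changes in the mix, recovery of 4-fold changes was 20.9 percent with residual and 56.7 percent with moderated spreads, and of 16-fold changes 74.2 and 98.5 percent. With moderated spreads and no 16-fold changes, 23 percent of 4-fold changes were recovered. With the replicate block and 16-fold changes in the mix, recovery of 4-fold changes was 0 percent with residual and 23.9 percent with moderated spreads, and of 16-fold changes 0 and 98.5 percent. Without 16-fold changes the block recovered 0 percent with either spread. The simulated arrays held no pairing, so a block could only cost precision there. Without the block, recovery of 2-fold changes was at most 1.5 percent in any of them. Most changes of 2-fold would therefore have been missed. No probe set was called with nothing changed, in any combination. With changes present and 16-fold changes in the mix, 4 of 67 calls with residual and 4 of 108 with moderated spreads were of unchanged probe sets. Without 16-fold changes, 2 of 25 calls with moderated spreads were.

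Alternatives were quantile normalization, median centring, a filter on low values, pseudocounts of 1 and 64, other variance models, array weights, a replicate block, an ordinary equal-variance test, removal of each array, removal of cross-hybridizing probe sets, a 2-fold minimum and means over probe sets. Added after results were seen were removal of both replicate 2 arrays, replicate 2 as a batch term, and the 3 prime to 5 prime ratio as a covariate. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.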

Results

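Leaf blades of an Os-LBD37 overexpressor rice line and of an empty vector line were compared on 3 arrays each. On each array, 50.9 to 55.4 percent of rice probe sets were above background. Correlations of log2 values were 0.9537 to 0.9801 within lines and 0.9391 to 0.9666 between them. Replicate 2 had only 0.9537 to 0.9565 with the other arrays of its own line. Replicates 1 and 3 correlated more closely than that between the lines, at 0.9627 to 0.9666. The probe set for a hygromycin resistance gene was bright on all arrays, at 21715 ± 2552 (SD, n = 3) in the empty vector line and 20085 ± 4055 (SD, n = 3) in the overexpressor. The mean log2 ratio of 3 prime to 5 prime control probe sets, a sign of RNA integrity, was 1.63 ± 0.64 (SD, n = 3) and 1.55 ± 0.14 (SD, n = 3), with an exact permutation p = 1. It was highest, at 2.37, on empty vector replicate 2.

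The comparison asks which leaf transcripts differ between a line made to overexpress Os-LBD37, a LOB-domain transcription factor gene, and an empty vector line. With 1 line per group, an effect of the gene cannot be told apart from other differences between the 2 lines. No probe set was identified for Os-LBD37, so its own level is not shown here. In Arabidopsis, relatives of this gene act on nitrogen-responsive genes. The ammonium transporter gene AMT3-2 rose by a log2 change of 2.68 ± 0.29 (SE, n = 3 per line; limma adjusted p = 0.0205). GLN1-1, for a cytosolic glutamine synthetase, rose by 2.26 ± 0.29 (adjusted p = 0.0331), and the urea transporter gene DUR3 rose by 2.21 ± 0.29 (adjusted p = 0.0355). The ammonium assimilation list as a whole did not pass by camera (adjusted p = 0.112), and 0 of 4 nitrate assimilation genes passed. JAZ2 and JAZ5, for repressors of jasmonate signalling, both rose. AMT3-2, DUR3 and JAZ2 were each measured by 1 probe set only, of the types that can cross-hybridize. The floral MADS-box gene Lhs1 and the florigen gene Hd3a both fell.

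Over all genes, 93 of 17905 passed, 57 higher and 36 lower in the overexpressor, and 2534 were under an unadjusted p of 0.05. Over probe sets, 59 of 57194 passed, 36 higher and 23 lower. With the replicate number as a block, 234 genes passed, 87 of them shared with the 93. Without both replicate 2 arrays, 239 genes passed, 63 of them shared, and the balance turned to 110 higher and 129 lower. Without overexpressor replicate 2 alone, 20 were higher and 30 lower. With single arrays removed, 4 to 50 genes passed, of which 4 to 32 were among the 93. The 2 lines did not overlap for 21.2 percent of genes, where chance gives 10 percent if the 6 arrays are exchangeable; that value leaves out the pairing by replicate number and the departure of replicate 2. Of the 93 genes, 21 had a name.

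JAZ2 was not above background on any empty vector array and was at least 44-fold higher in the overexpressor, at 2220 ± 266 (SD, n = 3; adjusted p = 0.00549). JAZ5 rose by 2.69 ± 0.38 (adjusted p = 0.0409; 0.0794 without both replicate 2 arrays). CAD6, in the family of cinnamyl alcohol dehydrogenases that make lignin precursors, rose by 2.99 ± 0.30 (adjusted p = 0.017). OsCASPL3A1, for a Casparian strip membrane protein relative, rose by 2.85 ± 0.43 (adjusted p = 0.0487; 0.0774 without both replicate 2 arrays). ASB2, for an anthranilate synthase subunit on the route to tryptophan, rose by 1.81 ± 0.25 (adjusted p = 0.0406). MPH1 rose by 1.90 ± 0.25 (adjusted p = 0.0355; 0.057 without both replicate 2 arrays). OsNrx1-1, for a nucleoredoxin, rose by 1.86 ± 0.27 (adjusted p = 0.0422; 0.0513 with the replicate block). The kinesin gene KIN14B was not above background on any empty vector array and was at least 1.3-fold higher (adjusted p = 0.0409; 0.0699 without both replicate 2 arrays).

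Lhs1 was above background on no overexpressor array and was at least 17.1-fold lower there, from 789.2 ± 228 (SD, n = 3; adjusted p = 0.00794). Hd3a fell by 2.40 ± 0.35 (adjusted p = 0.0447). BURP2 and BURP17, for BURP-domain proteins, had log2 changes of -4.68 ± 0.71 (adjusted p = 0.0491) and -2.89 ± 0.31 (adjusted p = 0.0191). BURP2 was above background on 1 of 3 overexpressor arrays, and with the others set to background its change was -4.33. KPHMT1, for a ketopantoate hydroxymethyltransferase of pantothenate synthesis, fell by 2.91 ± 0.41 (adjusted p = 0.0409; 0.0522 with the replicate block). OsVIT1, for a vacuolar iron transporter, fell by 2.29 ± 0.33 (adjusted p = 0.0422). The sugar transporter gene OsSWEET1a fell by 2.08 ± 0.22 (adjusted p = 0.0191). The kinesin gene KIN14K fell by 2.16 ± 0.28 (adjusted p = 0.0331), the calmodulin-like gene CML29 fell by 1.87 ± 0.20 (adjusted p = 0.0191) and the zinc finger homeodomain gene OsZHD10 fell by 1.79 ± 0.23 (adjusted p = 0.0331). The probe set used for KIN14K, 1 of 3 for this gene, is of a type that can cross-hybridize.

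**Figure D1:**
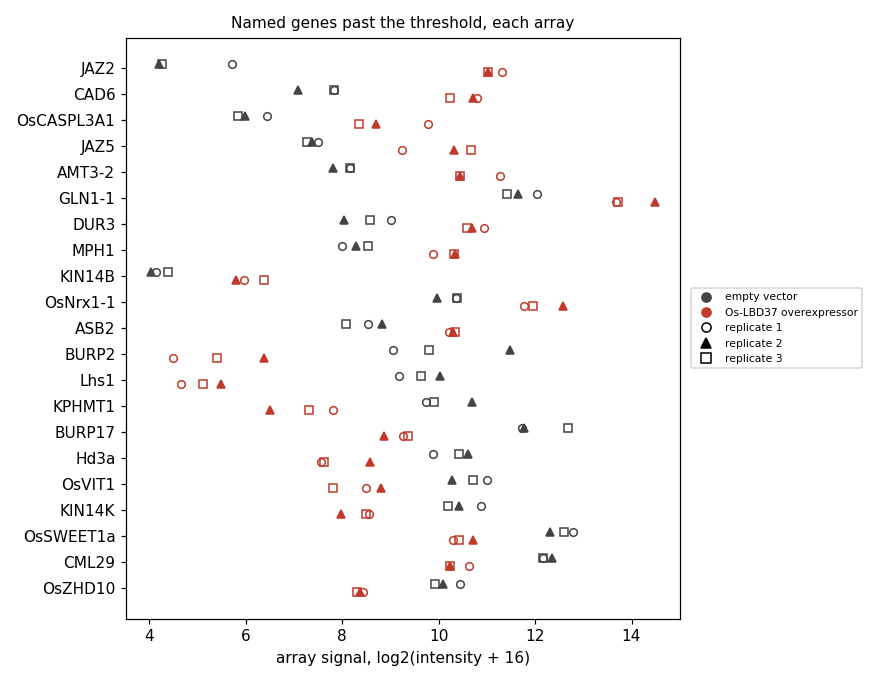
Array signal, as log2(intensity + 16), of the 21 named genes that passed, with 1 point per array. The 3 overexpressor points lie apart from the 3 empty vector points for each gene, as the choice of these genes required.

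Among unnamed genes, LOC4333227 had the largest rise. It was at 2.35 ± 0.37 (SD, n = 3) in the empty vector line, under background on all arrays, and at 10180 ± 2787 (SD, n = 3) in the overexpressor, at least 196-fold higher (adjusted p = 4.31e-05). LOC4331398 was at least 78.3-fold higher (adjusted p = 0.00198). Of the genes that passed, 8 were above background on all arrays of the overexpressor and on none of the empty vector line, and 7 the other way.

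Of 16 ammonium assimilation genes, 2 rose, AMT3-2 and GLN1-1, and 14 did not pass; adjusted over the list alone, 4 rose. The list did not pass by camera (adjusted p = 0.112). Of 4 nitrate assimilation genes, 0 passed over all genes and 1 rose adjusted over the list alone. That gene was NAR2.2, a partner of nitrate transporters, with a log2 change of 3.04 ± 0.71 (adjusted p = 0.11; 0.0461 with the replicate block and 0.0465 without both replicate 2 arrays). It was above background on only 1 of 3 empty vector arrays, and with the others set to background the change was 2.20. Of 14 flowering genes, Lhs1 and Hd3a fell and 12 did not pass; adjusted over the list alone, 3 fell and 1 rose. The flowering list was lower by fry (adjusted p = 0.0414) and did not pass by camera (adjusted p = 0.126).

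Of 40 jasmonate genes, 2 rose, JAZ2 and JAZ5, and 38 did not pass, and 4 rose adjusted over the list alone. The list was higher by camera (adjusted p = 0.000318), and its adjusted p = 0.603 with an estimated correlation. Of 27 phenylpropanoid and lignin genes, CAD6 rose and 26 did not pass, with 5 up and 1 down adjusted over the list alone. The list was higher (adjusted p = 0.00109; adjusted p = 0.603 with an estimated correlation). Of 8 LEA and dehydrin genes 0 passed, and 3 rose adjusted over the list alone. All 8 had log2 changes above 0, with a median of 1.79. Dhn1 had the smallest p, with 1.69 ± 0.35 (adjusted p = 0.0903; 0.0414 without both replicate 2 arrays). RAB21 and LEA19 were above background on 2 and 1 of 3 empty vector arrays, and with the others set to background their changes were 4.21 and 3.97. The list was higher by camera (adjusted p = 0.00265; adjusted p = 0.603 with an estimated correlation). Of 6 WRKY genes 0 passed and 3 rose adjusted over the list alone. OsWRKY62 had the smallest p, with 3.22 ± 0.66 (adjusted p = 0.0883; 0.0169 with the replicate block). The WRKY list was higher by camera (adjusted p = 0.00272; adjusted p = 0.603 with an estimated correlation).

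Of 25 cytosolic ribosome genes, 0 passed over all genes and 0 adjusted over the list alone. All 25 were lower, with a median log2 change of -0.21, and RPL39C had the smallest p, with -0.45 ± 0.25 (adjusted p = 0.483). The list was lower by camera (adjusted p = 0.00378; adjusted p = 0.875 with an estimated correlation, 0.531 after quantile normalization and 0.49 without both replicate 2 arrays). Of 6 sulfate genes, 0 passed and 3 fell adjusted over the list alone, among them SAT4, for a serine acetyltransferase, at -1.95 ± 0.36 (adjusted p = 0.0774). The list was lower (adjusted p = 0.0205; adjusted p = 0.603 with an estimated correlation, 0.059 with the replicate block). It was also not past by the ordinary test (0.08763), with the 3 prime to 5 prime ratio as a covariate (0.07887), without empty vector replicate 2 (0.05034) or 3 (0.054), or without overexpressor replicate 3 (0.06604). Among the added lists, the list of 17 plastid protease genes was lower by camera (adjusted p = 0.0132; adjusted p = 0.292 with an estimated correlation). Of these genes 15 were lower and 2 higher, 0 passed singly and 0 passed adjusted over the list alone. The list was not past after quantile normalization (adjusted p = 0.1265), without empty vector replicate 2 (0.1429) or without overexpressor replicate 3 (0.05934). CLPC3, for a subunit of the plastid Clp protease, had the smallest p. It was above background on no overexpressor array, was at least 2.33-fold lower there and did not pass (adjusted p = 0.146). The other 6 added lists, of aquaporins, endoplasmic reticulum chaperones, potassium transporters, metal transporters, abscisic acid and stress kinases, and PP2C phosphatases, did not pass by camera (adjusted p from 0.0799 to 0.875), and 0 of their members passed. Of the 39 fixed lists, 33 did not pass by camera (adjusted p from 0.0831 to 0.967). By fry, which tests whether a list's genes move on balance in 1 direction, none of the lists called by camera passed. Its adjusted p was 0.0776 for the phenylpropanoid and WRKY lists, 0.14 for jasmonate, 0.144 for sulfate, 0.172 for LEA and dehydrin genes, 0.224 for plastid proteases and 0.525 for cytosolic ribosome genes. Flowering was the 1 list past by fry. Other splits of the 6 arrays called up to 7 lists, against 6 for the 2 lines.

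**Figure D2:**
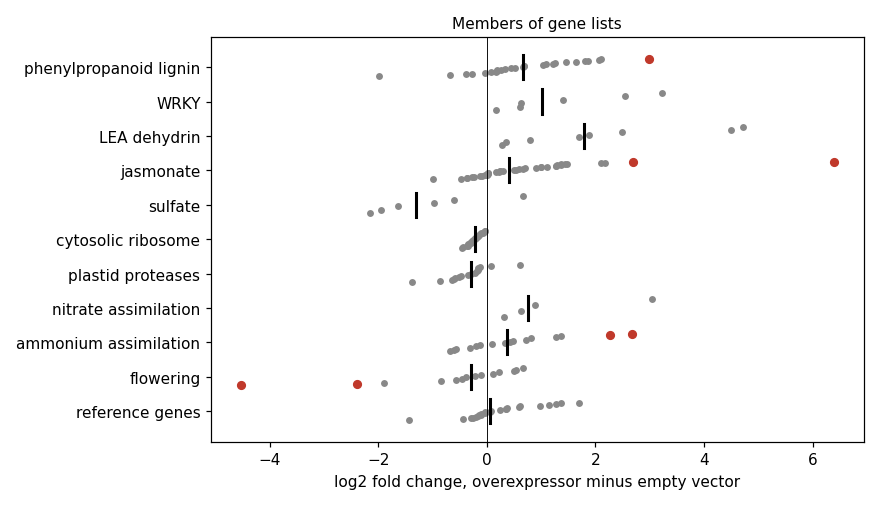
Log2 fold changes of list members, with 1 point per gene, larger red points for genes that passed and a bar at the list's median. The 8 LEA and dehydrin genes lie above 0 and the 25 cytosolic ribosome genes below it.

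Of 26 iron homeostasis genes, OsVIT1 fell and 25 did not pass, with 3 down and 1 up adjusted over the list alone. Of 43 sucrose and trehalose genes, OsSWEET1a fell and 42 did not pass, with 1 down adjusted over the list alone. Neither list passed by camera (adjusted p = 0.276 and 0.837). Of 10 photosystem and light-harvesting genes and 5 Calvin cycle genes, 0 passed (camera adjusted p = 0.0831 and 0.109). GOS5 had the smallest p of the first, with a log2 change of -0.81 ± 0.23 (adjusted p = 0.174), and PPE of the second, with -0.51 ± 0.21 (adjusted p = 0.337). Of 63 cell wall genes, 0 passed and 4 rose adjusted over the list alone. CESA6, for a cellulose synthase, had the smallest p, with 2.24 ± 0.35 (adjusted p = 0.0542; 0.0406 with the replicate block). Chalcone synthase, CHS, the entry enzyme of flavonoid synthesis, had a log2 change of 3.31 ± 0.84 and did not pass (adjusted p = 0.136). Its change was 2.17 without both replicate 2 arrays and 2.44 without overexpressor replicate 2. AS2, the 1 LOB-domain gene with a name here, was not above background on any empty vector array and did not pass (adjusted p = 0.168). Of 24 reference genes 0 passed, and 5 rose adjusted over the list alone, and AC2, for an actin, had the smallest p, with 1.36 ± 0.28 (adjusted p = 0.0903).

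The replicate 2 arrays of both lines differed from the others in circadian clock genes. The morning gene CCA1 was at 5241 on empty vector replicate 2, against 602.1 and 682.1, and at 18630 on overexpressor replicate 2, against 611.3 and 624.2. The evening gene OsPCL1 went the other way, at 1401 against 20090 and 22350, and at 1275 against 16870 and 17830. Between the lines, 0 of 7 clock genes passed, and DTH7 had the smallest p, with -0.39 ± 0.36 (adjusted p = 0.7). In replicate 2, 157 genes departed over 4-fold in both lines in 1 direction, and 6 in opposite directions.

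**Figure D3:**
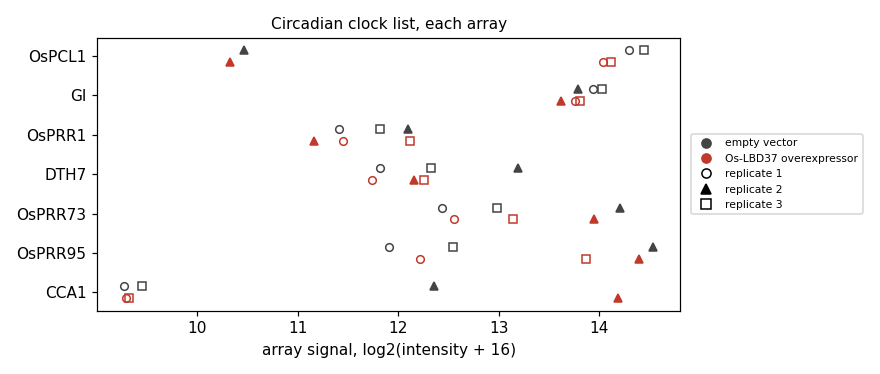
Array signal, as log2(intensity + 16), of the 7 circadian clock genes, with 1 point per array and filled triangles for replicate 2. The triangles lie low for OsPCL1 and high for CCA1 in both lines.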

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

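No result met a rule for this part. Groups of 3 arrays were not tested for outlying samples, the study has 1 contrast, and the hygromycin probe set outside the main comparison was not higher in the overexpressor (exact permutation p = 0.8, where 0.1 is the smallest possible).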

How the results depend on the processing

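Removal of both replicate 2 arrays, the batch term and the ratio covariate were chosen after results were seen, as was removal of arrays for the control probe sets.

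The number of genes that passed, 93, was 169 after median centring, 404 with array weights, 234 with the replicate block, 494 with replicate 2 as a batch term, 243 with the 3 prime to 5 prime ratio as a covariate and 239 without both replicate 2 arrays. It was 1 by the ordinary test. Without empty vector replicate 1, 2 or 3 it was 4, 30 and 7, and without overexpressor replicate 1, 2 or 3 it was 12, 50 and 4; 4, 22, 7, 9, 32 and 4 of these were among the 93.

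The 59 probe sets became 146 after median centring, 154 with the low filter, 39 with a pseudocount of 64, 97 with a robust trend, 232 with array weights, 6 by the ordinary test, 27 without both replicate 2 arrays and 292 with replicate 2 as a batch. Removal of single arrays gave 9, 19 and 9 in the empty vector line and 6, 16 and 5 in the overexpressor. With the replicate block there were 60, of which 33 were shared.

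The 6 lists became 0 with an estimated correlation and 11 without empty vector replicate 1; removal of other single arrays gave 4 to 7. After quantile normalization 4 were up and 1 down. The sulfate and plastid protease losses are in the report. The cytosolic ribosome list was also lost with array weights (adjusted p = 0.109), without empty vector replicate 3 (0.0819) and without overexpressor replicate 2 (0.234). Removal of single arrays moved the jasmonate list's adjusted p between 1.18e-05 and 0.00532, and that of the LEA list between 4.43e-05 and 0.0477.

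All 21 named genes that passed kept direction, which their choice by non-overlapping groups fixed for array removal. Without cross-hybridizing probe sets, 17 of 18 stayed past (AMT3-2, DUR3 and JAZ2 not measured). 19 stayed past with the replicate block and 17 without both replicate 2 arrays, but 0 by the ordinary test. Removal of both replicate 2 arrays also moved 7 past the threshold: Dhn1, NAR2.2, LOGL3, GSTU6, NAC45, OsPIP1;3 and OsPP2C29. With replicate 2 as a batch term all 21 stayed past and 15 other named genes moved past. Among these were SAT4, AC2 and Dhn1 (limma adjusted p = 0.0476, 0.0401 and 0.0305). Without empty vector replicate 1, 2 or 3, 1, 4 and 1 stayed past, and without overexpressor replicate 1, 2 or 3, 3, 8 and 0. Among genes that had not passed, CDC2-1 turned to 0.1 without cross-hybridizing probe sets and PRX112 to 0.1 without both replicate 2 arrays. Besides the calls in the report, the replicate block moved CIPK14, OsPIP1;3, HAK10 and OsPP2C29 past the threshold (adjusted p = 0.0169, 0.025, 0.0406 and 0.0461) and changed no other call of a named gene or list.

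The difference in the 3 prime to 5 prime ratio, -0.09, turned to 0.28 without empty vector replicate 2 and 0.22 without both replicate 2 arrays, and otherwise lay between -0.28 and -0.01. The cause was not tested.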

Other observations

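The tests of the replicate 2 shift, of the lists with the 3 prime to 5 prime ratio and without replicate 2, and the comparison of splits were chosen after results were seen. The test with an estimated correlation was planned, but its use to weigh an explanation came after its result was seen.

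The replicate 2 arrays stood apart in both lines. A candidate explanation is that these leaves were taken at another time of day. The clock list's median absolute shift, from shifts averaged over the lines, was 1.3. It was larger than that of 99.9 percent of 1000 random gene sets. These sets were drawn from all measured genes and were not matched for signal. The list has only 7 genes: GI hardly moved (mean shift -0.18), and OsPRR1 went opposite ways in the lines (0.49 and -0.63). RNA integrity alone would tie the shift to the 3 prime to 5 prime ratio. The excess of that ratio in the overexpressor was 0.17 of that in the empty vector line. The slope between the lines' shifts was 0.51 ± 0.01 (SE from leaving out each chromosome, 8952 expressed genes). With 1 replicate 2 array per line, this SE leaves out the spread between arrays, so the slope cannot decide on RNA integrity. No biological explanation by line was tested, since both lines share the pattern, and part of the shift may still follow RNA integrity or another difference between harvests.

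The jasmonate, phenylpropanoid, LEA and WRKY lists were higher in the overexpressor. All 4 stayed past with the 3 prime to 5 prime ratio as a covariate. The ratio differed by only -0.09 between the lines and was highest on empty vector replicate 2 (2.37). The covariate could therefore hardly change the fitted line differences, so RNA integrity stays open as a cause. All 4 also stayed past without both replicate 2 arrays, but the LEA list only just (adjusted p = 0.04996). With replicate 2 as a batch term, also added after results were seen, its camera adjusted p was 0.00264. Those of the jasmonate, phenylpropanoid and WRKY lists were 0.00111, 0.00111 and 0.00553. Each line has 1 replicate 2 array, so a shift shared by both lines cancels in the line difference. A part from a replicate 2 harvest that differed between the lines stays open. With an estimated correlation 0 of them stayed past. That setting also raised the unadjusted camera p of lists with a negative estimate. For flowering (estimate -0.051) it rose from 0.0386 to 0.0928, and for nitrate assimilation (-0.108) from 0.0506 to 0.118. The loss therefore cannot decide whether genes that move together within a list account for the small p-values of the 4 lists. That explanation stays open. An effect of the overexpressed gene stays open.

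LOC4333227 was bright on all overexpressor arrays and under background in the empty vector line. Its 10 nearest measured genes had a median log2 change of -0.21, from -0.51 to 0.38, which argues against a change of the whole neighbourhood. A transcript of the introduced construct may be the source, but the tables do not name this gene, so this was not tested. Differences between the 2 lines other than the construct stay open as well.

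The 6 arrays allow 10 splits, too few for a share under 0.05. The real split called 93 genes and 59 probe sets, each in 1 of the 10 splits, and the highest other called 0. For lists, 2 of the 10 splits called as many: the real one called 6 and the highest other 7, a split that parts 1 pair of replicate numbers. Among the 4 splits that part 3 pairs, the highest other called 5 lists and 0 genes.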
